A study of Mus musculus with 45 samples.

How the data were processed

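The deposited table holds transcripts per 1e+06 (TPM) per gene symbol and library, computed by the authors and not rescaled between libraries. A second deposited table of the authors holds log2 values, which the numbers themselves show to be log2 of an estimated read count plus 0.5, per 1e+06 of the library's total plus 1. Estimated counts solved from that table summed to the total implied by its floor within 0.081% in every library, so the depth of each library could be read from it. The solved counts are not a count table, since between 1.5% and 35% of the low values per library lay within 0.01 of a whole number. The TPM listed in a library add up to between 92.1% and 96% of 1e+06, so part of the transcripts is absent from the table. No per-sample column of either table was left unused.

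The submitters' processing notes name kallisto, limma, GRCm38 and mm10 without versions, and neither the transcript set nor the way transcripts were summed to genes is given in the sources used here. Per the labels, polyA RNA of sorted viable cells was extracted, cDNA was made with a SMART-seq kit and libraries with Nextera XT. The series text and the sample labels name different SMART-seq kits. Both a HiSeq and a NextSeq instrument are named there, and which library ran on which is not stated. Symbols are those of the table, which uses older names such as Igj for Jchain. Of the 30317 symbols, 28480 were found in a mouse gene name table, and no coordinates come with the files.

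TPM were divided by a median-ratio size factor per library (range 0.418 to 1.33), a pseudocount of 1 was added, and log2 was taken. Because log2(value + pseudocount) pulls low values together, the change of a gene near 0 TPM is understated. Genes with a TPM of at least 1 in at least 3 libraries were tested, which left 15614 of 30317. Group values are means of scaled TPM with the standard deviation (SD) over 3 libraries, and log2 fold changes carry a standard error (SE) from the model. One limma model with 15 group means was fitted to all 45 libraries, with a mean-variance trend and robust moderation. Every comparison is a contrast of these means, with Benjamini-Hochberg adjustment over the genes tested within it, and a gene was called at an adjusted p below 0.05. No label says that replicates are separate animals or cultures, so a p measures the spread of these samples, pooled over all 15 groups.

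Lists of marker, pathway and signalling genes were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and the first set of other settings. The 30 lists with at least 5 tested members were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Each list call was repeated with the correlation estimated per list. Of 660 list tests 294 were called, and 135 with the estimated correlation. For each list the number of called members is given over all genes tested and adjusted over the list alone. A list in which no gene passes can still be called, because camera weighs small shifts of many members.

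Genes were named by rule. Notch pathway genes, B cell fate genes and Dll1, which the DL1 stroma carries, were looked at in every comparison. Then came the 6 largest increases and 6 largest decreases among called genes whose 3 libraries in one group all lay outside the range of the other group, with a mean of at least 10 scaled TPM in a group. Averages and interactions required the call alone. For each called list, up to 4 called members with the largest change were added. Variable, diversity and joining segments and unnamed gene models were left out. Some genes that the rule names are not reported here. Actb was named after its values were seen.

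The first set of other settings held TPM as deposited, quantile normalization, the authors' log2 table in the same model, removal of 316 immunoglobulin genes, a pseudocount of 0.1, no filter, a filter at 5 TPM, the replicate number as a term (the replicate block), only the groups compared, another reference for the Blimp1+ sort, and leaving out each library in turn. Where leaving out a library leaves 2 in its group, that group is assumed to vary like the others. Added after seeing the data were a fit without 10 libraries that stood apart, a fit with a score for that class as a term, and restrictions of the averages and time comparisons to 44 and 68 h without those libraries.

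In a self-test, values of 15614 genes were drawn from a normal distribution at the mean and residual SD of each gene, and 200 genes received a known change. For the DL1 effect with LPS at 44 h, 12% of the genes changed by a log2 of 1 and 54% of those changed by 2 were called, with 2 unchanged genes called. For the interaction of DL1 and LPS the shares were 1% and 21% with 0 unchanged genes called, and for the average DL1 effect 85% and 99% with 9 unchanged genes called. Such draws hold no divergent library, so power and false calls may differ in the data. Other single comparisons were not simulated, and a gene not called is not shown to be unchanged.

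Software was R 4.3.3 with limma 3.58.1 and data.table (1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.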

Results

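RNA was measured as polyA transcripts, in TPM (transcripts per 1e+06), in follicular B cells from the spleens of mice that carry GFP in 1 copy of Blimp1, the gene whose product drives plasma cell formation. The cells were cultured on OP9, a bone marrow stromal line, or on OP9-DL1, the same line made to carry the Notch ligand Delta-like 1, and are called OP9 and DL1 cells here. Cultures received no stimulus, lipopolysaccharide (LPS, a ligand of TLR4) or anti-IgM F(ab')2 (a ligand of the B cell receptor), each stimulus at 10 µg/mL. The series has 45 libraries in 15 groups of 3, with stimulated cells at 20, 44 and 68 h on each stroma, unstimulated cells at 68 h on each stroma, and Blimp1+ cells sorted from DL1 cultures with LPS. Blimp1+ cells carry no time in the labels. The estimated read number per library ran from 3.07 M to 29.1 M (M for 1e+06). Unstimulated DL1 cells had the lowest group mean (4.62 ± 1.34 M, SD, n = 3) and OP9 cells with anti-IgM at 44 h the highest (14.2 ± 13 M). Dll1, the ligand that the stroma carries, measured 0.55 to 41 TPM in the 24 DL1 libraries and 0 to 3.7 TPM in the 21 OP9 libraries.

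Libraries of one group were not always alike. A score was defined after seeing the data as the mean log2 TPM of 100 genes highest in replicate 3 of 4 groups at 68 h, minus that of 100 genes lowest there. It lay between -1.87 and 0.13 in 35 libraries and between 2.18 and 7.24 in the other 10, called divergent here. They are all 3 DL1 libraries with LPS at 20 h, all 3 OP9 libraries with anti-IgM at 20 h, and at 68 h replicate 3 of unstimulated OP9, OP9 with LPS, DL1 with LPS and OP9 with anti-IgM. Actb, an actin gene of the score, measured 12400 to 85300 TPM in divergent libraries and 217 to 2970 TPM in others. At 20 h divergence coincides with a stroma, so it cannot be told from the DL1 effect. At 44 h no library is divergent. Within OP9 with LPS at 20 h replicate 3, not divergent, stood apart (Myc 735 against 337 and 365 scaled TPM). Genes of a stroma list took 0.566% to 2.14% of 1e+06 TPM in the 3 unstimulated OP9 libraries and 0.00703% to 0.0806% in the other 42.

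**Figure D1:**
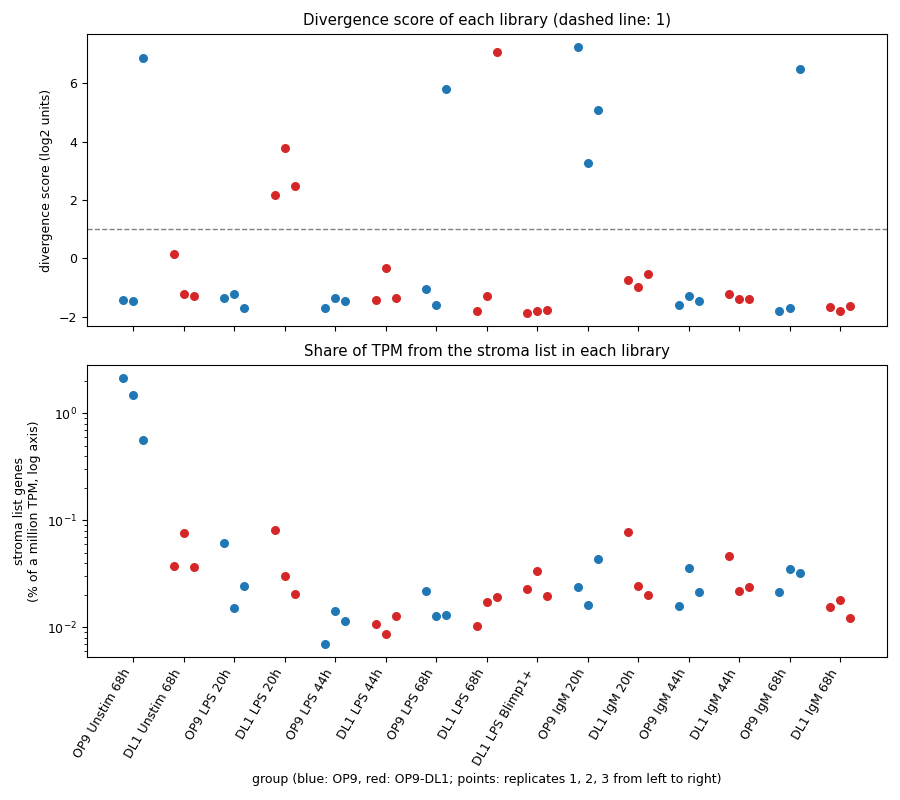
Top, divergence score in log2 units for 45 libraries by group (OP9 blue, DL1 red), with a dashed line at 1 that parts 10 divergent libraries (2.18 to 7.24) from 35 others (-1.87 to 0.13). Bottom, the percent of 1e+06 TPM in the stroma list on a log axis, with the 3 unstimulated OP9 libraries between 0.566 and 2.14.

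Values after ± below are standard errors of log2 fold changes in limma, or standard deviations of scaled TPM. The DL1 effect is the log2 value of DL1 cells minus that of OP9 cells at the same stimulus and time. Every group has n = 3. Of 660 list tests 135 were called with an estimated correlation, and with TPM as deposited 24.

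Which genes the Notch ligand changes without another stimulus was asked in unstimulated cells at 68 h. Dtx1, a regulator induced by Notch, was higher in DL1 cells by a log2 of 3.02 ± 0.57 (84.4 ± 16.5 against 11.2 ± 7.21 TPM, adjusted p = 0.00011). Nrarp, a feedback inhibitor of Notch, was higher by 0.92 ± 0.28 (adjusted p = 0.011). Irf4, which steers activated B cells toward plasma cells, was higher by 2.42 ± 0.36 (16.8 ± 2.53 against 3.03 ± 2.5 TPM, adjusted p = 3.1e-06), and Nr4a1, an early gene of receptor signalling, by 3.28 ± 0.79 (adjusted p = 0.0016). Hes1, another Notch target, had an effect of 1.56 ± 1.14 that was not called, and one of 3.65 that was called without OP9 replicate 3, the divergent one. Plk1, a mitotic kinase, was higher in DL1 cells by 3.24 ± 0.49 (adjusted p = 3.5e-06). Ptn, a growth factor of stromal cells, was lower by 7.96 (log2 -7.96 ± 0.53, 0.892 ± 0.885 against 475 ± 215 TPM), and the chemokine Cxcl12 by 5.52 (log2 -5.52 ± 0.88, 67.5 ± 30.1 against 5200 ± 4400 TPM). Saa3, an acute phase gene, averaged 2940 ± 2920 TPM in OP9 cells and was listed at 0 in DL1 cells. Of the genes tested, 4184 were called, 1341 higher and 2843 lower in DL1 cells, and 6581 without divergent libraries. Nrarp and Irf4 were not called with only the groups compared.

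By list, 24 of 30 B cell receptor pathway genes were higher in unstimulated DL1 cells and 25 adjusted over the list alone (median 1.96, adjusted p = 1.4e-15, but adjusted p = 0.061 with an estimated correlation). Of 26 B cell identity genes 19 were higher, and adjusted over the list alone 22 were higher and 1 lower (median 1.82, adjusted p = 1.4e-12, but adjusted p = 0.065 with an estimated correlation). The mitosis list had 15 of 28 genes higher, 18 adjusted over the list alone (median 1.32, adjusted p = 3.2e-12, and 0.038 with an estimated correlation). For 28 ribosome biogenesis genes the median was 0.64 with 7 higher, also 7 adjusted over the list alone (adjusted p = 5.2e-05, and 0.0027 with an estimated correlation). Of 14 Notch targets 4 were higher and 1 lower, the same numbers adjusted over the list alone (median 0.22, adjusted p = 0.048, but adjusted p = 0.15 with an estimated correlation). The marginal zone list, genes of the B cell subset that needs NOTCH2, had 5 of 20 members higher and 7 lower with a median of 0.12 and was not called (adjusted p = 0.43). The stroma list was lower in DL1 cells for 21 of 26 genes, 22 adjusted over the list alone (median -3.99, adjusted p = 6.2e-13, but adjusted p = 0.065 with an estimated correlation). Without divergent libraries the mitosis (1.75) and ribosome biogenesis (0.51) medians were not called with an estimated correlation, and that of Notch targets was 0.66. The OP9 libraries here, 1 of them divergent, are those with the high stroma list share. Deposited TPM gave 2004 higher and 1982 lower (median of all genes 0.148, against -0.209), quantile normalization 2511 and 2135 (0.048), and the authors' log2 values 1640 and 1297 (0.289).

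What the ligand adds to a 20 h response to LPS is the question of the next comparison, in which all 3 DL1 libraries are divergent. Ccl22, a chemokine that attracts T cells, was lower in DL1 cells by 3.56 (log2 -3.56 ± 0.42, 4.02 ± 1.19 against 61.1 ± 29.8 TPM, adjusted p = 1.9e-06). The cytokine Il6 was lower by 2.96 (log2 -2.96 ± 0.52, adjusted p = 0.00039, and -3.63 without a call in the authors' log2 table) and the costimulatory gene Cd86 by 1.66 (log2 -1.66 ± 0.35, adjusted p = 0.0028). Fcer2a, the follicular marker CD23, was lower by 2.18 (log2 -2.18 ± 0.44, 10.3 ± 3.27 against 49.5 ± 11.8 TPM, adjusted p = 0.0019). Igj, the listed name of the J chain of secreted antibody, was higher by 2.35 ± 0.5 (99.7 ± 10.2 against 20.3 ± 10.6 TPM, adjusted p = 0.0029). Hes1 was higher by 5.34 ± 1.14 (47.5 ± 22.2 against 0.13 ± 0.225 TPM, adjusted p = 0.0028), and by 3.23 with the divergence score as a term. NF-kB targets were lower for 8 of 22, and 12 adjusted over the list alone (median -1.09, adjusted p = 4e-08, and 0.0031 with an estimated correlation). Of 28 DNA replication genes 9 were higher, 14 adjusted over the list alone (median 0.76, adjusted p = 8.7e-09, and 0.0077 with an estimated correlation). In the list of 25 plasma cell genes 3 were higher and 1 lower, and 5 and 1 adjusted over the list alone (median 0.57, adjusted p = 0.015, and 0.021 with an estimated correlation). In total 1340 genes were called, 599 higher and 741 lower, and 2502 with the score as a term. The count ran from 638 to 1847 with 1 library left out. With only the groups compared Igj, Fcer2a, Il6 and Cd86 were not called.

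At 44 h with LPS, the same question has no divergent library. Igj was higher in DL1 cells by 2.85 ± 0.5 (22 ± 1.5 against 2.28 ± 0.953 TPM, adjusted p = 0.0035), though its call was lost without OP9 replicate 2 (2.58). Bnip3, a mitochondrial gene induced by low oxygen, was higher by 2.84 ± 0.51 (451 ± 59.3 against 61.9 ± 3.77 TPM, adjusted p = 0.0035), and the glycolytic enzyme Pgk1 by 1.39 ± 0.23 (1050 ± 75 against 403 ± 25.6 TPM, adjusted p = 0.0017). Ighg2b, a switched antibody constant region, was higher by 2.27 ± 0.39 (367 ± 38.6 against 75.7 ± 10.5 TPM, adjusted p = 0.0025). Ccl22 was lower by 2.95 (log2 -2.95 ± 0.42, 4.17 ± 0.939 against 38.8 ± 7.37 TPM, adjusted p = 0.00022), as was Ms4a4c, a membrane gene of the CD20 family (log2 -2.92 ± 0.44, adjusted p = 0.00041). Glycolysis had 2 of 23 genes higher and 9 adjusted over the list alone (median 0.98, adjusted p = 2.4e-28, and 0.00039 with an estimated correlation). The list of mTORC1 and ATF4 targets, which serve amino acid supply, had 3 of 24 higher and 10 adjusted over the list alone (median 0.68, adjusted p = 2.4e-26, and 1.3e-07 with an estimated correlation). Of the 25 plasma cell genes 1 was higher, and 1 adjusted over the list alone (median 0.26, adjusted p = 3.7e-06, and 5.4e-05 with an estimated correlation). Dtx1 had an effect of 0.4 and Hes1 of 1.56, neither called. All told 25 genes were called, 22 higher and 3 lower, and 109 without divergent libraries elsewhere. With 1 library left out there were 14 to 17. Bnip3 (2.8), Pgk1 (1.35) and Ighg2b (2.23) were not called with TPM as deposited, nor were they (2.84, 1.37, 2.27) or Ccl22 (-3.24) in the authors' log2 table. Under other scalings the split was 11 higher and 5 lower (TPM as deposited), 17 and 8 (quantile) or 4 and 2 (the authors' log2 table).

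By 68 h with LPS few genes were called, and replicate 3 on each stroma is divergent. Igj was lower in DL1 cells by 3.61 (log2 -3.61 ± 0.5, 1.65 ± 0.957 against 30 ± 4.38 TPM, adjusted p = 2e-04). Tnip3, an inhibitor of NF-kB signalling, was lower by 2.13 (log2 -2.13 ± 0.29, 4.32 ± 2.09 against 21.2 ± 3.96 TPM, adjusted p = 2e-04), and was not called with a pseudocount of 0.1 (-2.39) or in the authors' log2 table (-2.58). Fcer2a had an effect of 1.64 ± 0.44 that was not called (adjusted p = 0.36), and Dtx1 one of 0.01. The 30 interferon response genes had a median of 0.65, with 2 higher adjusted over the list alone (adjusted p = 2.8e-10, and 0.0011 with an estimated correlation). For DNA replication the median was -0.3 (adjusted p = 1.4e-06, and 0.036 with an estimated correlation), and for mitosis -0.39 (adjusted p = 1.5e-08, but adjusted p = 0.078 with an estimated correlation). Without divergent libraries DNA replication (-0.23) was not called with an estimated correlation. Of 8 called genes 3 were higher and 5 lower, and 15 and 8 of 23 without divergent libraries, 13 and 9 with no filter. There were 5 calls without OP9 replicate 1 or 2. Quantile normalization gave 2 higher and 11 lower, and the authors' log2 values 0 higher and 1 lower (limma, 497 genes at an unadjusted p under 0.05 in the main scaling). In that table the median of all genes was -0.086, against 0.072. Igj and Tnip3 were not called with only the groups compared.

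With anti-IgM the same contrast asks how the ligand alters the response to the B cell receptor, and at 20 h all 3 OP9 libraries are divergent. Igj was higher in DL1 cells by 3.77 ± 0.5 (237 ± 60.8 against 16.1 ± 2.1 TPM, adjusted p = 3.8e-05). Ccna2, a cyclin of S and G2 phase, was higher by 2.21 ± 0.3 (78 ± 22.9 against 15.7 ± 1.13 TPM, adjusted p = 3.8e-05). Slc7a5, an amino acid transporter, was higher by 3.07 ± 0.56 (39.7 ± 8.27 against 4.49 ± 2.93 TPM, adjusted p = 0.0011), and Rrp12, a ribosome assembly factor, by 2.25 ± 0.41 (adjusted p = 0.0011). Of 28 ribosome biogenesis genes 12 were higher, and adjusted over the list alone 12 were higher and 1 lower (median 0.53, adjusted p = 1e-04, and 0.0017 with an estimated correlation). Plasma cell genes had 5 of 25 higher and 1 lower, the same numbers adjusted over the list alone (median 0.59, adjusted p = 0.0046, and 0.013 with an estimated correlation). The count of called genes was 3135, 1512 higher and 1623 lower, and 315 with the score as a term (220 higher, 95 lower). The count ran from 946 to 4149 with 1 library left out. With TPM as deposited 1659 were higher and 1013 lower (median of all genes 0.251, against -0.028) and the authors' log2 values 2528 and 1071 (median 0.4).

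No library is divergent at 44 h with anti-IgM. Itgb7, an integrin chain that guides homing, was lower in DL1 cells by 3.07 (log2 -3.07 ± 0.54, 2.46 ± 0.352 against 28 ± 2.96 TPM, adjusted p = 0.002). Pcp4, a calmodulin regulator, was higher by 3.29 ± 0.47 (21.8 ± 3.12 against 1.34 ± 0.37 TPM, adjusted p = 0.00015), and Npm1, a nucleolar factor of ribosome assembly, by 1.12 ± 0.19 (1310 ± 8.55 against 601 ± 41.7 TPM, adjusted p = 0.0019). Of 28 ribosome biogenesis genes 3 were higher, and 18 adjusted over the list alone (median 0.87, adjusted p = 3.7e-23, and 3.1e-10 with an estimated correlation). Oxidative phosphorylation had 1 of 31 higher, also 1 adjusted over the list alone (median 0.41, adjusted p = 1.4e-09, and 0.017 with an estimated correlation). Follicular B cell genes were lower for 4 of 16, and 7 adjusted over the list alone (median -1.17, adjusted p = 2.7e-11, and 0.017 with an estimated correlation). Cell cycle inhibitors were lower for 2 of 17, also 2 adjusted over the list alone (median -1.03, adjusted p = 7.5e-05, and 0.011 with an estimated correlation). Genes of heat and handling stress, called stress genes below and a list that shares no member with ribosome biogenesis, had 1 of 12 higher and 3 adjusted over the list alone (median 0.52, adjusted p = 7.4e-06, and 0.00063 with an estimated correlation). The stroma list was called upward with 0 of 26 genes called by limma, where 1335 had an unadjusted p under 0.05 (median 0.4, adjusted p = 0.0017, but adjusted p = 0.42 with an estimated correlation). Dtx1 (-0.22), Hes1 (-0.16) and Myc (0.37) were not called. In all 132 genes were called, 69 higher and 63 lower, and 911 without divergent libraries elsewhere. With 1 library left out there were 26 to 46. TPM as deposited gave 9 higher and 17 lower, without Npm1 (1.04), and the authors' log2 table called neither Npm1 (1.11) nor Itgb7 (-3.5) and Pcp4 (3.9).

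At 68 h with anti-IgM, OP9 replicate 3 is divergent. Igj was higher in DL1 cells by 3.17 ± 0.5 (94.7 ± 16.1 against 10.5 ± 5.12 TPM, adjusted p = 0.00053). Fdps, an enzyme of cholesterol synthesis, was higher by 1.4 ± 0.22 (182 ± 6.29 against 69.2 ± 16.2 TPM, adjusted p = 0.00051), and the mitochondrial enzyme gene Gcat by 2.33 ± 0.4 (adjusted p = 0.0016). Wfdc17, a secreted protease inhibitor of the WAP family, was lower by 3.38 (log2 -3.38 ± 0.48, 19.7 ± 5.19 against 212 ± 32.9 TPM, adjusted p = 0.00018). Of 24 cholesterol synthesis genes 5 were higher, and 14 adjusted over the list alone (median 0.93, adjusted p = 1.1e-12, and 0.0018 with an estimated correlation). Oxidative phosphorylation had 3 of 31 higher and 17 adjusted over the list alone (median 0.69, adjusted p = 6.7e-15, and 0.0031 with an estimated correlation). Ribosome biogenesis had 1 of 28 higher and 4 adjusted over the list alone (median 0.34, adjusted p = 3.8e-06, and 0.00048 with an estimated correlation). Called genes numbered 206, 106 higher and 100 lower, and 855 without divergent libraries. With 1 library left out there were 29 to 446. Quantile normalization gave 203 higher and 83 lower, with a median of all genes of 0.001 against -0.164, and the authors' log2 table had a median of 0.062 and TPM as deposited of 0. Igj, Fdps, Gcat and Wfdc17 were not called with only the groups compared.

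**Figure D2:**
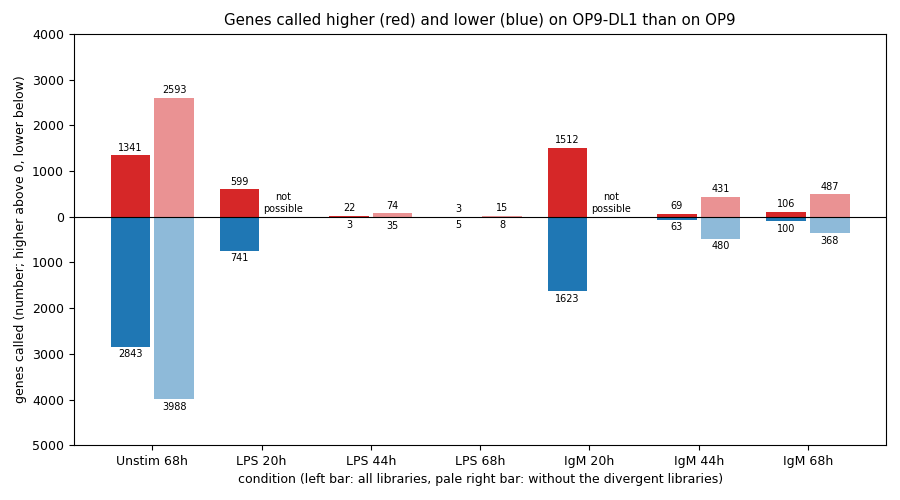
Genes called higher (red) and lower (blue) in DL1 than OP9 cells in 7 settings, with all libraries on the left and without the 10 divergent libraries in pale on the right, where 20 h could not be fitted. Unstimulated cells had 4184 calls with all libraries and 6581 without the divergent ones, and LPS at 68 h had 8 and 23.

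**Figure D3:**
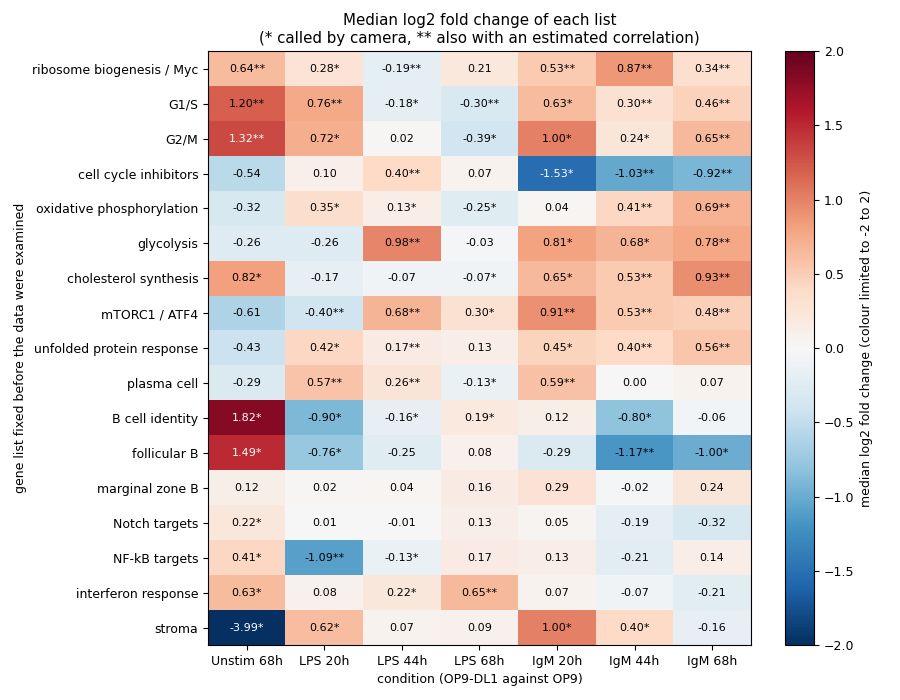
Median log2 fold change of DL1 against OP9 cells for 17 gene lists in 7 settings, limited in colour to -2 and 2, with * for a camera call and ** for a call that also holds with an estimated correlation. Ribosome biogenesis with anti-IgM at 44 h has a median of 0.87 and the stroma list in unstimulated cells one of -3.99.

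The mean of the 7 DL1 effects asks what the ligand does whatever the stimulus and time. Ighg2b was higher in DL1 cells by 1.49 ± 0.15 (adjusted p = 1.5e-08) and Igj by 1.07 ± 0.19 (adjusted p = 0.00024). The Igj mean pools effects of both signs, from -3.61 with LPS at 68 h and -2.49 in unstimulated cells (adjusted p = 0.00023) to 3.77 with anti-IgM at 20 h. Dtx1 was higher by 0.78 ± 0.22 (adjusted p = 0.014), and Prdm1, the gene of BLIMP1, by 0.42 ± 0.13 (adjusted p = 0.023). Over the stimulated 44 and 68 h pairs without divergent libraries Dtx1 had -0.09 and Prdm1 0.01, neither called. Dll1 itself was higher by 2.01 ± 0.27 (adjusted p = 4.8e-06). Bcl6, the repressor that holds B cells in the germinal centre state, was lower by 0.75 (log2 -0.75 ± 0.13, adjusted p = 0.00022), as was Wfdc17 (log2 -2.17 ± 0.18, adjusted p = 6.4e-10). Mitosis had 16 of 28 genes higher and 23 adjusted over the list alone (median 0.46, adjusted p = 1.8e-19, and 0.0032 with an estimated correlation). Of 28 ribosome biogenesis genes 15 were higher, and 19 adjusted over the list alone (median 0.43, adjusted p = 1.9e-15, and 4.1e-08 with an estimated correlation). Of 25 plasma cell genes 7 were higher and 1 lower, and 8 and 3 adjusted over the list alone (median 0.17, adjusted p = 0.0013, and 0.004 with an estimated correlation). Over the stimulated 44 and 68 h pairs without divergent libraries the plasma cell median of 0.08 was not called, nor the mitosis median of 0.13 with an estimated correlation, and ribosome biogenesis (0.3) kept its call. With LPS at 44 h alone ribosome biogenesis was called downward (median -0.19, adjusted p = 0.0074, and 0.021 with an estimated correlation). The stress genes were higher in the mean for 3 of 12, also 3 adjusted over the list alone (median 0.15, adjusted p = 0.012, and 0.027 with an estimated correlation), with 0.24 over those pairs. Among Notch targets 3 were higher and 3 lower (median -0.01, adjusted p = 0.59). The mean called 2174 genes, 806 higher and 1368 lower, and 800 over the stimulated 44 and 68 h pairs without divergent libraries. The split was 718 higher and 731 lower with TPM as deposited, 1085 and 787 with quantile normalization and 806 and 416 with the authors' log2 table (median of all genes 0.073, against -0.084).

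The response to LPS on plain OP9, against unstimulated cells at 68 h, asks what TLR4 signalling does without the added ligand. Plk1 rose by 6.08 ± 0.49 (156 ± 9.3 against 1.36 ± 0.552 TPM, adjusted p = 9.1e-12) and Fdps by 5.06 ± 0.22 (978 ± 38.5 against 29.9 ± 12.4 TPM, adjusted p = 3.7e-18). Aldoc, a glycolytic aldolase, rose by 7.44 ± 0.54 (545 ± 81 against 3.57 ± 4.42 TPM, adjusted p = 8.1e-13). The switched constant region Ighg3 rose by 5.31 ± 0.43 (adjusted p = 1.2e-11), Dtx1 by 2.24 ± 0.57 (adjusted p = 0.0025) and Prdm1 by 1.91 ± 0.34 (adjusted p = 2.7e-05). All 28 mitosis genes rose, also 28 adjusted over the list alone (median 3.46, adjusted p = 2.2e-39, and 2.4e-05 with an estimated correlation). Cholesterol synthesis rose in 23 of 24 genes, 23 adjusted over the list alone (median 2.66, adjusted p = 3.9e-23, and 2.1e-05 with an estimated correlation). Of 22 NF-kB targets 13 rose and 1 fell, and 14 and 2 adjusted over the list alone (median 1.28, adjusted p = 1.5e-06, and 0.0027 with an estimated correlation). The stroma list fell in 25 of 26 genes, 26 adjusted over the list alone (median -5.13, adjusted p = 2.6e-18, and 0.032 with an estimated correlation), and it is high in the unstimulated OP9 libraries. With 1 divergent library in each group, 4862 genes were called, 1556 higher and 3306 lower. Quantile normalization gave 2417 higher and 2135 lower (median of all genes 0.029, against -0.303), the authors' log2 values 1542 and 2104 (median -0.181), and TPM as deposited had a median of -0.109. Dtx1 and Prdm1 were not called with only the groups compared.

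The response to anti-IgM on OP9 at 68 h asks the same of the B cell receptor. Mki67, a marker of dividing cells, rose by 3.65 ± 0.25 (29.3 ± 0.358 against 1.54 ± 1.05 TPM, adjusted p = 6e-13). Rasd1, a small GTPase, rose by 4.75 ± 0.34 (51.6 ± 20.7 against 0.923 ± 0.665 TPM, adjusted p = 1.6e-12), and Irf4 by 2.2 ± 0.36 (adjusted p = 1.3e-05). Ifit1, an interferon response gene, fell by 3.77 (log2 -3.77 ± 0.52, 3.5 ± 2.89 against 56.7 ± 24.9 TPM, adjusted p = 5.2e-07). All 28 mitosis genes rose, also 28 adjusted over the list alone (median 2.98, adjusted p = 1.5e-37, and 5.4e-05 with an estimated correlation). Of 28 DNA replication genes 24 rose, and adjusted over the list alone 26 rose and 1 fell (median 1.9, adjusted p = 3.8e-23, and 1.9e-05 with an estimated correlation). Notch targets rose in 6 of 14 and fell in 1, the same numbers adjusted over the list alone (median 0.65, adjusted p = 0.0085, but adjusted p = 0.096 with an estimated correlation). The stroma list fell in 25 of 26 genes, 25 adjusted over the list alone (median -4.87, adjusted p = 5.4e-20, and 0.031 with an estimated correlation). Replicate 3 is divergent in both groups, and without it the stroma median (-5.78) was not called with an estimated correlation. There were 3811 called genes, 1244 higher and 2567 lower, and 6174 without divergent libraries. Quantile normalization gave 1968 higher and 2061 lower (median of all genes 0.103, against -0.113). Irf4 was not called with only the groups compared.

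On DL1 stroma the response to LPS at 68 h asks what TLR4 signalling adds to cells that see the Notch ligand, and 1 LPS library is divergent. Fdps rose by 3.25 ± 0.22 (773 ± 74.7 against 82.9 ± 27.6 TPM, adjusted p = 1.8e-12), Pgk1 by 3.26 ± 0.23 (1090 ± 73.8 against 116 ± 37.9 TPM, adjusted p = 2.4e-12), and the regulatory cytokine Il10 by 3.47 ± 0.59 (adjusted p = 9.2e-05). S1pr1, the receptor that lets lymphocytes leave tissue, fell by 4.61 (log2 -4.61 ± 0.43, 5.45 ± 2.62 against 147 ± 23.8 TPM, adjusted p = 1.7e-09). Cd1d1, a marginal zone marker, fell by 2.08 (log2 -2.08 ± 0.3, adjusted p = 7.7e-06). Mitosis rose in 26 of 28 genes, 28 adjusted over the list alone (median 2.05, adjusted p = 3.6e-34, and 7.6e-05 with an estimated correlation). Of 24 cholesterol synthesis genes 21 rose, 22 adjusted over the list alone (median 1.95, adjusted p = 4.8e-26, and 7.6e-06 with an estimated correlation). Glycolysis rose in 13 of 23 genes, 16 adjusted over the list alone (median 1.85, adjusted p = 1.8e-21, and 0.00097 with an estimated correlation). Of 17 cytokine and regulatory B cell genes 8 rose and 1 fell, and 8 and 2 adjusted over the list alone (median 0.66, adjusted p = 2.3e-05, and 0.00097 with an estimated correlation). The stroma list fell in 6 of 26 genes, 8 adjusted over the list alone (median -1.4, adjusted p = 3.7e-07, but adjusted p = 0.18 with an estimated correlation). The response called 1230 genes, 772 higher and 458 lower, with 2668 without divergent libraries and 715 without unstimulated replicate 2. With unscaled TPM there were 411 higher and 559 lower (median of all genes -0.256, against 0) and the authors' log2 values 271 and 374 (median -0.477).

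Neither group of the response to anti-IgM on DL1 at 68 h holds a divergent library. Igj rose by 4.69 ± 0.5 (94.7 ± 16.1 against 2.89 ± 1.74 TPM, adjusted p = 4.6e-08). Pdcd1, the inhibitory receptor PD-1, rose by 4.56 ± 0.63 (60.7 ± 4.17 against 1.73 ± 1.02 TPM, adjusted p = 4.8e-06), and Ube2c, a mitotic enzyme, by 3.63 ± 0.34 (284 ± 0.8 against 23.5 ± 10.6 TPM, adjusted p = 5.5e-09). Cr2, the complement receptor CD21, fell by 2.55 (log2 -2.55 ± 0.39, 13.7 ± 0.568 against 88.1 ± 27 TPM, adjusted p = 2.3e-05), and Fcer2a by 2.09 (log2 -2.09 ± 0.44, adjusted p = 0.0015). Ifit3 fell by 4.08 (log2 -4.08 ± 0.62, 2.5 ± 0.644 against 57.7 ± 2.51 TPM, adjusted p = 2e-05). All 28 mitosis genes rose, also 28 adjusted over the list alone (median 2.48, adjusted p = 1.4e-49, and 5e-06 with an estimated correlation). Interferon response genes fell in 13 of 30, and adjusted over the list alone 16 fell and 1 rose (median -1, adjusted p = 2e-09, and 0.001 with an estimated correlation). Oxidative phosphorylation rose in 13 of 31 genes, 23 adjusted over the list alone (median 0.85, adjusted p = 6.9e-14, and 0.0028 with an estimated correlation). The count of 1468 called genes had 811 higher and 657 lower, and 4291 were called without divergent libraries elsewhere. The count ran from 891 to 1195 with 1 library left out. TPM as deposited gave 470 higher and 979 lower (median of all genes -0.28, against -0.132), the authors' log2 values 490 and 625 (median -0.363), and quantile normalization had a median of -0.001.

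Whether the ligand changes the response to LPS at 68 h is tested by the difference between the LPS response on DL1 and that on OP9. Plk1 differed by a log2 of -4.2 ± 0.69 (adjusted p = 4.1e-05), so its response was smaller on DL1. Dtx1 differed by -3.01 ± 0.81 (adjusted p = 0.0081), and by -2.38 without unstimulated OP9 replicate 1, where it was not called. Irf4 differed by -2.11 ± 0.52 (adjusted p = 0.0037, and -1.4 without unstimulated OP9 replicate 1). Ptn differed by 7.96 ± 0.75 and the chemokine Ccl5 by 7.45 ± 0.83 (adjusted p = 7.4e-09 and 1.5e-07). Mitosis was lower for 15 of 28 genes, 17 adjusted over the list alone (median -1.52, adjusted p = 2.3e-15, and 0.017 with an estimated correlation). DNA replication was lower for 15 of 28, and adjusted over the list alone 18 were lower and 1 higher (median -1.53, adjusted p = 4.1e-11, and 0.0056 with an estimated correlation). Without divergent libraries DNA replication (-1.54) was not called with an estimated correlation. The stroma list was higher for 21 of 26 genes, 21 adjusted over the list alone (median 3.87, adjusted p = 2e-11, but adjusted p = 0.12 with an estimated correlation), and the unstimulated OP9 libraries, where that list is high, enter this difference. In all 2574 genes were called, 1925 higher and 649 lower, and 4249 were called without divergent libraries. Quantile normalization gave 1281 higher and 1275 lower (median of all genes -0.042, against 0.32), the authors' log2 values 399 and 516 (median -0.307), and TPM as deposited had a median of -0.102. Dtx1 and Irf4 were not called with only the groups compared.

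For anti-IgM the same difference asks whether the ligand changes the response to the B cell receptor. Cr2 differed by -2.91 ± 0.55 (adjusted p = 0.00034) and Fcer2a by -2.58 ± 0.63 (adjusted p = 0.0038). Igj differed by 5.67 ± 0.71 (adjusted p = 1.6e-06), Asns, which makes asparagine, by 5.03 ± 0.9 (adjusted p = 0.00017), and Calr, a chaperone of the endoplasmic reticulum, by 2.47 ± 0.57 (adjusted p = 0.0024). Calr was not called with TPM as deposited (2.19), nor Fcer2a in the authors' log2 table (-2.78). Follicular B cell genes were lower for 10 of 16, 12 adjusted over the list alone (median -2.34, adjusted p = 5.5e-09, but adjusted p = 0.087 with an estimated correlation). Of 14 Notch targets 4 were lower, and adjusted over the list alone 7 were lower and 1 higher (median -1.09, adjusted p = 0.0055, but adjusted p = 0.087 with an estimated correlation). The stroma list was higher for 19 of 26 genes, 21 adjusted over the list alone (median 3.78, adjusted p = 2.4e-12, but adjusted p = 0.087 with an estimated correlation). The 2497 called genes were 1781 higher and 716 lower, with 5746 called without divergent libraries. There were 1498 without unstimulated OP9 replicate 1 and 4137 without replicate 3, which is divergent. Quantile normalization gave 1548 higher and 1200 lower (median of all genes -0.088, against 0.014), the authors' log2 values 400 and 298 (median -0.222), and TPM as deposited had a median of -0.171. Cr2, Fcer2a and Calr were not called with only the groups compared.

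**Figure D4:**
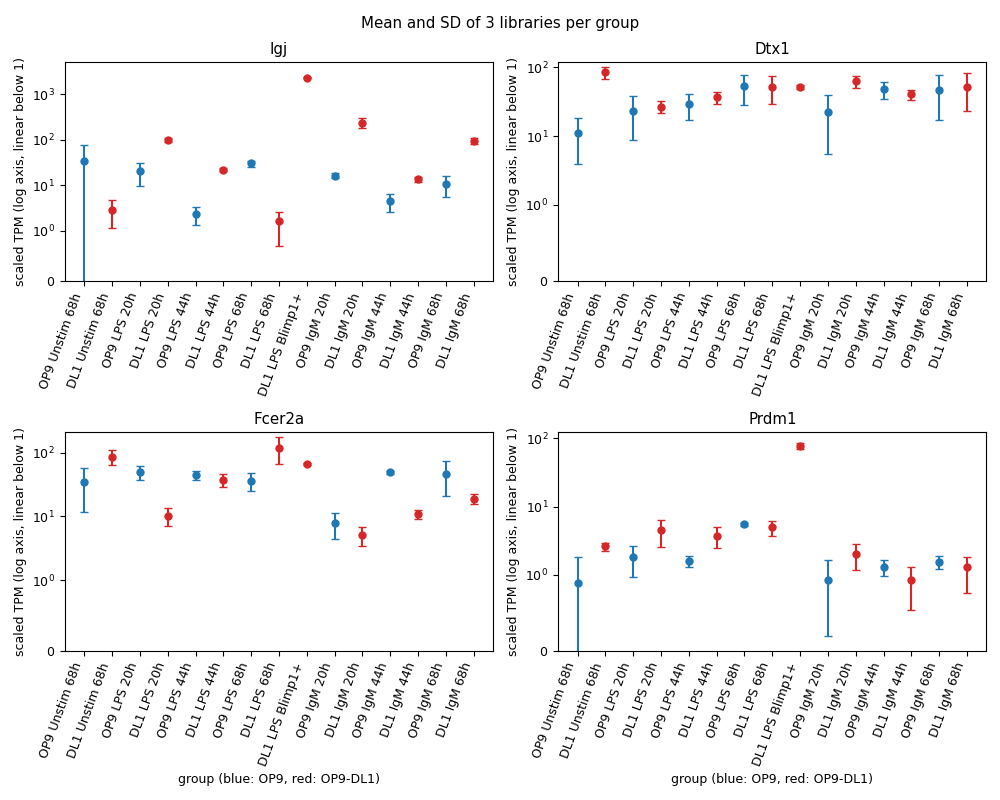
Scaled TPM of Igj, Dtx1, Fcer2a and Prdm1 by group, as means with bars of 1 SD over 3 libraries, on an axis that is linear below 1 and logarithmic above, with bars that would pass below 0 ended at 0. Igj averaged 2280 TPM in Blimp1+ cells and 1.65 TPM in DL1 cells with LPS at 68 h.

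Whether the ligand acts differently under the TLR4 and the B cell receptor stimulus is asked by the mean DL1 effect with LPS minus that with anti-IgM, each over 3 times. Ccl22 differed by -2.48 ± 0.34 (adjusted p = 0.00013), Ccl3 by -1.9 ± 0.34 (adjusted p = 0.0016) and Igj by -2.27 ± 0.41 (adjusted p = 0.002), all lower with LPS. Hspd1, a mitochondrial chaperone, differed by -0.95 ± 0.18 (adjusted p = 0.0028). Ribosome biogenesis was lower for 13 of 28 genes, 14 adjusted over the list alone (median -0.49, adjusted p = 5e-07, and 8.8e-05 with an estimated correlation). Of 24 cholesterol synthesis genes 12 were lower, and adjusted over the list alone 16 were lower and 1 higher (median -0.83, adjusted p = 8.9e-09, and 0.012 with an estimated correlation), with a median of -0.54 with the score as a term. There were 1684 called genes, 1004 higher and 680 lower, with 571 over 44 and 68 h without divergent libraries and 182 with the score as a term. At 20 h the divergent libraries are DL1 with LPS and OP9 with anti-IgM, so divergence enters this difference with 1 sign. Quantile normalization gave 501 higher and 731 lower (median of all genes -0.034, against 0.111), the authors' log2 values 907 and 1006 (median -0.169), and TPM as deposited had a median of -0.074. The count ran from 690 to 2844 with 1 library left out.

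Whether the DL1 effect with LPS changes over time is tested by the effect at 68 h minus that at 20 h. Igj differed by -5.96 ± 0.71 (adjusted p = 6.7e-06), its effect being 2.35 at 20 h and -3.61 at 68 h. Fcer2a differed by 3.81 ± 0.63 (adjusted p = 6e-04), Egr1, an immediate early gene, by 4.92 ± 0.83 (adjusted p = 0.00085), and Cox6a2, a subunit of cytochrome oxidase, by 6.82 ± 0.64 (adjusted p = 3e-08). DNA replication was lower for 3 of 28 genes, 10 adjusted over the list alone (median -1.09, adjusted p = 3.5e-13, and 0.0014 with an estimated correlation). NF-kB targets were higher for 6 of 22, and adjusted over the list alone 8 were higher and 1 lower (median 1.28, adjusted p = 9.1e-07, and 0.0037 with an estimated correlation). Activation and costimulation genes were higher for 5 of 19, 8 adjusted over the list alone (median 1.23, adjusted p = 4.1e-08, and 0.0076 with an estimated correlation). All DL1 libraries at 20 h are divergent, and there were 381 calls (251 higher, 130 lower) with all libraries and 1822 with the score as a term. From 44 to 68 h without divergent libraries there were 8, 5 of them among the 381, and neither Cox6a2 (1.81) nor Fcer2a (2.1) was called. In that fit DNA replication (-0.06) was not called, nor activation genes (0.36) with an estimated correlation, and NF-kB targets had 0.36. With 1 library left out the count ran from 136 to 804. Quantile normalization gave 93 higher and 80 lower, and the authors' log2 table had a median of all genes of -0.057, against 0.087. With only the groups compared there were 14 calls, without Fcer2a and Egr1.

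For anti-IgM the change of the DL1 effect between 20 and 68 h was called by limma for 1 gene, which was lower, while 1381 had an unadjusted p under 0.05. Igj had a difference of -0.6 ± 0.71 (adjusted p = 0.82), Dtx1 of -1.44 ± 0.81 (adjusted p = 0.62) and Hes1 of -1.86 ± 1.61 (adjusted p = 0.74). The median of 31 oxidative phosphorylation genes was 0.68 (adjusted p = 2.4e-08, but adjusted p = 0.14 with an estimated correlation). From 44 to 68 h without divergent libraries the oxidative phosphorylation median was 0.3. All OP9 libraries at 20 h are divergent. The count ran from 0 to 56 with 1 library left out.

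How the response to LPS develops was asked within each stroma, at 68 h against 20 h. On OP9 Fdps rose by 1.93 ± 0.22 (adjusted p = 1.3e-07). Il6 fell by 3.97 (log2 -3.97 ± 0.52, adjusted p = 1.7e-06), the chemokine Ccl3 had -3.72 ± 0.41 (adjusted p = 7e-08), and the growth regulator Myc fell by 1.82 (log2 -1.82 ± 0.38, 132 ± 47 against 479 ± 222 TPM, adjusted p = 0.00095). Ribosome biogenesis fell in 23 of 28 genes, 25 adjusted over the list alone (median -1.68, adjusted p = 1.4e-26, and 5.8e-11 with an estimated correlation). Of 12 stress genes 5 fell and 1 rose, and 5 and 2 adjusted over the list alone (median -0.66, adjusted p = 0.0024, and 0.013 with an estimated correlation), with -1.32 from 44 to 68 h and -0.84, not called with an estimated correlation, without divergent libraries. Mitosis rose in 17 of 28 genes, 23 adjusted over the list alone (median 1.41, adjusted p = 1.6e-13, and 0.013 with an estimated correlation). Of 17 cell cycle inhibitors 5 rose and 1 fell, and 8 and 1 adjusted over the list alone (median 1.51, adjusted p = 0.00045, and 0.014 with an estimated correlation). There were 1995 calls, 1121 higher and 874 lower, and 3433 without divergent libraries, replicate 3 at 68 h being one. Without divergent libraries the inhibitors had a median of 0.97, and from 44 to 68 h neither Fdps (0.48) nor the mitosis list (-0.24) was called. Quantile normalization gave 888 higher and 990 lower (median of all genes -0.018, against 0.072). With only the groups compared 2 genes were called, and none of those named here.

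On DL1 the same comparison with LPS sets 3 divergent libraries at 20 h against 1 at 68 h. Igj fell by 5.32 (log2 -5.32 ± 0.5, 1.65 ± 0.957 against 99.7 ± 10.2 TPM, adjusted p = 1.9e-09). Fcer2a rose by 3.34 ± 0.44 (119 ± 53.2 against 10.3 ± 3.27 TPM, adjusted p = 8.8e-07) and H2-Ob, which tunes antigen loading on class II molecules, by 4.91 ± 0.37 (adjusted p = 8.6e-11). Ribosome biogenesis fell in 25 of 28 genes, 27 adjusted over the list alone (median -1.72, adjusted p = 2.2e-25, and 1e-10 with an estimated correlation). Of 12 stress genes 4 fell and 2 rose, and 4 and 3 adjusted over the list alone (median -0.54, adjusted p = 0.0071, and 0.032 with an estimated correlation, a call lost with the score as a term at -0.55). The stroma list fell in 4 of 26, also 4 adjusted over the list alone (median -0.98, adjusted p = 3.5e-05, but adjusted p = 0.26 with an estimated correlation), and had 0.34 without a call from 44 to 68 h. DNA replication fell in 13 of 28, 17 adjusted over the list alone (median -0.95, adjusted p = 5.3e-10, and 0.0045 with an estimated correlation). Interferon response genes rose in 15 of 30, 16 adjusted over the list alone (median 1.07, adjusted p = 0.00011, and 0.032 with an estimated correlation). With the divergence score as a term the interferon median (0.89) was not called with an estimated correlation. The 2945 calls were 1786 higher and 1159 lower, and 5092 with the score as a term. Quantile normalization gave 1091 higher and 1226 lower (median of all genes -0.001, against 0.193).

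With anti-IgM on OP9, 68 h was set against 20 h, where all 3 libraries are divergent. Fcer2a rose by 2.32 ± 0.44 (adjusted p = 0.0012) and Cd1d1 by 1.93 ± 0.3 (adjusted p = 8.8e-05). The ribosome assembly factor Wdr12 fell by 1.73 (log2 -1.73 ± 0.25, adjusted p = 3.5e-05). From 44 to 68 h without divergent libraries, Fcer2a (0.32), Cd1d1 (0.05) and Wdr12 (-0.34) were not called. Mitosis rose in 22 of 28 genes, 23 adjusted over the list alone (median 1.49, adjusted p = 7.3e-18, and 0.0077 with an estimated correlation). Ribosome biogenesis fell in 13 of 28, also 13 adjusted over the list alone (median -0.72, adjusted p = 1.7e-08, and 2.1e-05 with an estimated correlation). Of 12 stress genes 2 fell and 1 rose, and 4 and 1 adjusted over the list alone (median -0.46, adjusted p = 0.009, and 0.037 with an estimated correlation). Oxidative phosphorylation fell in 13 of 31, 18 adjusted over the list alone (median -0.75, adjusted p = 4.2e-09, and 0.037 with an estimated correlation). From 44 to 68 h without divergent libraries the mitosis median turned to -0.39, and those of ribosome biogenesis and oxidative phosphorylation were -0.28 and -0.38, and the stress median of -0.31 was not called with an estimated correlation. Calls numbered 1463, 950 higher and 513 lower. There were 469 to 3723 with 1 library left out, the highest without replicate 3 at 68 h, which is divergent. Quantile normalization gave 584 higher and 503 lower (median of all genes -0.007, against 0.109), TPM as deposited had a median of 0.21 and the authors' log2 table of 0.375. With only the groups compared limma called 0 genes, so Fcer2a, Cd1d1 and Wdr12 lost their calls, where 4039 had an unadjusted p under 0.05 in the full model.

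On DL1 the change with anti-IgM between 20 and 68 h involves no divergent library. Cd1d1 rose by 1.86 ± 0.3 (31.5 ± 2.94 against 8.14 ± 2.31 TPM, adjusted p = 0.00043) and Siglecg, an inhibitor of B cell receptor signalling, by 2.2 ± 0.43 (adjusted p = 0.0036). Ccl3 fell by 2.1 (log2 -2.1 ± 0.41, adjusted p = 0.0036) and Rrs1, a ribosome assembly factor, by 1.67 (log2 -1.67 ± 0.3, adjusted p = 0.0015). Mitosis rose in 10 of 28 genes, 23 adjusted over the list alone (median 1.14, adjusted p = 7.9e-24, and 0.00095 with an estimated correlation). Ribosome biogenesis fell in 7 of 28, 17 adjusted over the list alone (median -0.9, adjusted p = 1.5e-20, and 1.5e-09 with an estimated correlation). The stress genes fell in 2 of 12, 3 adjusted over the list alone (median -0.66, adjusted p = 0.0047, and 0.028 with an estimated correlation, a call lost without divergent libraries elsewhere). The stroma list fell in 1 of 26, also 1 adjusted over the list alone (median -0.81, adjusted p = 6.4e-05, but adjusted p = 0.3 with an estimated correlation). Of 20 marginal zone genes 3 rose, also 3 adjusted over the list alone (median 0.24, adjusted p = 0.004, and 0.031 with an estimated correlation). Of 14 Notch targets 2 fell, also 2 adjusted over the list alone (median -0.4, adjusted p = 0.0047, but adjusted p = 0.068 with an estimated correlation). From 44 to 68 h neither mitosis (-0.02) nor Notch targets (-0.2) were called. The marginal zone median (0.24) was not called with an estimated correlation without divergent libraries elsewhere, and was 0.12 with the score as a term. There were 363 called genes, 229 higher and 134 lower, and 1704 without divergent libraries elsewhere. With 1 library left out there were 128 to 224. Unscaled TPM gave 51 higher and 51 lower, without Cd1d1 (1.78) and Siglecg (2.11), and from 44 to 68 h Cd1d1 had 0.58 without a call. Ccl3 was not called in the authors' log2 table (-2.18). Rrs1 was not called with only the groups compared.

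Blimp1+ cells sorted from DL1 cultures with LPS were set against DL1 cells with LPS at 68 h to ask what marks the cells that switch on Blimp1. Igj rose by 9.82 ± 0.5 (2280 ± 69.7 against 1.65 ± 0.957 TPM, adjusted p = 6.4e-16). Prdm1 rose by 3.73 ± 0.34 (77.6 ± 8.06 against 4.97 ± 1.22 TPM, adjusted p = 1.3e-09) and Xbp1, the transcription factor of the secretory program, by 3.9 ± 0.62 (1320 ± 89.2 against 107 ± 66.2 TPM, adjusted p = 5.4e-05). Ighm, the constant region of IgM, rose by 3.65 ± 0.43 (29900 ± 1160 against 2690 ± 1360 TPM, adjusted p = 2.5e-07), while Ighd, that of IgD, fell by 2.46 (log2 -2.46 ± 0.46, 40.1 ± 0.597 against 225 ± 5.21 TPM, adjusted p = 0.00067). Against DL1 cells with LPS at 44 h Ighd had -0.12, and with quantile normalization Ighm had 2.27, neither called. Antibody genes took 21.5% ± 0.493 of 1e+06 TPM in Blimp1+ cells and 2.43% ± 1.2 in the reference. Pax5, which maintains B cell identity, had a difference of -0.8 ± 0.41 (adjusted p = 0.47) and Bach2, which represses Prdm1, of -0.24, neither called. The unfolded protein response rose in 18 of 30 genes, 24 adjusted over the list alone (median 1.62, adjusted p = 2.1e-29, and 2.1e-07 with an estimated correlation). Of 25 plasma cell genes 14 rose, 16 adjusted over the list alone (median 1.84, adjusted p = 6.9e-29, and 3.9e-12 with an estimated correlation). Regulators of antibody secretion rose in 6 of 11 and fell in 1, and in 10 and 1 adjusted over the list alone (median 2.14, adjusted p = 4.9e-16, and 0.00029 with an estimated correlation). Marginal zone genes rose in 4 of 20, 5 adjusted over the list alone (median 0.46, adjusted p = 9.5e-05, and 0.0025 with an estimated correlation), with a median of 0.22 without divergent libraries. The stroma list was called upward with 0 of 26 genes called by limma, where 1798 had an unadjusted p under 0.05 (median 1.24, adjusted p = 2.8e-05, but adjusted p = 0.64 with an estimated correlation), and 3 were called against DL1 cells at 44 h (1.49). Called genes numbered 443, 400 higher and 43 lower, against 1227 higher and 692 lower with the 44 h reference. There were 257 without replicate 3 of the reference, which is divergent. TPM as deposited gave 220 higher and 123 lower (median of all genes -0.181, against -0.005), and the authors' log2 table had a median of 0.102. Xbp1 was not called with only the groups compared.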

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

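Chosen only after results were seen were the tests on genomic DNA, on RNA of stromal cells and on the share of B cells, the counts over other splits of the samples, and the fits without divergent libraries or with the divergence score as a term.

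The first pattern is the 10 divergent libraries. Across 15416 genes with known sequence, which are not independent replicates, the shift of the divergent libraries in the 4 mixed groups at 68 h correlated with GC content at a Spearman rho of -0.26, -0.25, -0.28 and -0.19, so a GC bias is neither shown nor excluded by bounds of 0.3 and 0.1. Transcript length reached at most -0.08 in size, and 0.01 nearest to 0, which argues against a length bias. Summed TPM of olfactory and vomeronasal receptors, a sign of genomic DNA, passed all others in 3 of 10 divergent libraries (6 without 1 other). It was 14.7 to 32.9 in DL1 with LPS at 20 h (others 7.11 to 224), arguing against such DNA there but not elsewhere. Satellite RNA was 0.0444% to 41.3% of TPM (others to 12.3%). No biological explanation was tested, since the design has no group that parts these libraries.

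The second pattern is the difference of the unstimulated OP9 libraries from the DL1 ones. RNA of stromal cells is a candidate source, as 21 of 26 stroma list members were higher in OP9 and 0 lower by limma, among 5758 genes at an unadjusted p under 0.05 in that comparison. Of the 26, 21 also averaged at least 1 TPM in the libraries other than unstimulated OP9 and 0 stand on another list, and the sort named in the labels is on viability. A lower share of B cells would lower B cell identity genes alike, and 19 of 26 were lower and 0 higher in OP9, which does not part a lower share from lower expression per cell. An effect of the Notch ligand on the B cells themselves stays open, untested.

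The third pattern is the rise of ribosome biogenesis genes on DL1 with anti-IgM, with a list median of 0.87 at 44 h. No library at 44 h is divergent, and at 68 h the median was 0.34, and 0.36 without the divergent one. The scaling of libraries (0.8 to 0.89 over 3 other scalings) and any one library (0.83 to 0.93 with each of the 6 left out) are argued against. So is RNA of stromal cells, which in OP9 unstimulated libraries brings at least 4.79 TPM of the stroma list per TPM of the ribosome list, so the rise of 3130 TPM would need 15000 TPM, and at most 438 TPM were listed in a DL1 library (291 ± 128 TPM on DL1 and 229 ± 96.6 on OP9, SD, list median 0.4, called but not with an estimated correlation). Heat and handling stress genes rose with it (median 0.52), which was not tested as a source, so an effect of the Notch ligand on growth is a hypothesis that the same data raised.

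A test of the difference between the DL1 and OP9 responses to LPS called 2574 genes. Of these Dtx1 (-3.01), Nrarp (-1.11), Irf4 (-2.11), Nr4a1 (-3.21) and Plk1 (-4.2) had a lower signed log2 response on DL1, and Ptn (7.96) and Ccl5 (7.45) a higher one. These are differences of signed values, and Ptn fell on OP9 (log2 -8.43). Without unstimulated OP9 replicate 1 Dtx1 was -2.38, not called, and Irf4 -1.4. Nrarp lost its call with 9 left-out libraries (-1.25 to -0.96) and Nr4a1 with 8 (-4.32 to -2.22). Both, Dtx1 and Irf4 lost it with only the groups compared. Saa3 (6.76) is listed at 0 in a whole group, so it depends on the pseudocount.

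The same test for anti-IgM called 2497 genes. Dtx1 (-2.79), Nrarp (-1.31), Cr2 (-2.91), Fcer2a (-2.58), Irf4 (-2.16) and Cd55 (-3.86) had a lower log2 response on DL1, and Igj (5.67), C3 (7.05), Asns (5.03), Calr (2.47) and Saa3 (10.5, with groups listed at 0) a higher one. On DL1 Cr2 (-2.55), Fcer2a (-2.09) and Cd55 (-3.46) fell, and on OP9 C3 (-7.12) did. The unstimulated OP9 libraries enter these differences too. Leaving out a library ended the call of Dtx1 in 4 cases (-3.53 to -2.15) and of Nrarp in 1 (-1.45 to -1.22), and with only the groups compared those 2 lost it, as did Cr2, Fcer2a, Irf4 and Calr.

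A test of the DL1 effect with LPS against that with anti-IgM called 1684 genes. Igj (-2.27), Ccl4 (-4.12), Ccl3 (-1.9), Ccl22 (-2.48), Ube2c (-1.34), Ccna2 (-1.17), Mcm7 (-1.09), Cycs (-0.8) and Hspd1 (-0.95) were lower with LPS, and Hes1 (2.92) and Slc24a5 (5.37) higher. With the divergence score as a term Hes1 had 0.67 and Slc24a5 1.68, and with 21 of the left-out libraries Hes1 lost its call (2.38 to 3.28).

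A test of the DL1 effect at 68 h against 20 h called 381 genes with LPS and 1 with anti-IgM. With LPS, Fcer2a (3.81), Cox6a2 (6.82), Egr1 (4.92), Slc7a1 (4.86), Cth (3.74), Trib3 (3.1) and Il6 (2.69) had a larger value at 68 h, and Igj (-5.96) and Plk1 (-3.02) a smaller one. Trib3 lost its call with 5 left-out libraries (2.55 to 3.76) and Il6 with 8 (2.24 to 3.41). From 44 to 68 h without divergent libraries Trib3 (-1.75) and Cth (-0.37) turned. Fcer2a, Egr1, Slc7a1, Trib3, Plk1 and Il6 lost their calls with only the groups compared.

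Other splits of the same libraries were counted for each comparison. Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05, and the real split gave the highest count unless said. The real and highest other counts were 4184 and 1692 in unstimulated cells, 1340 and 177, 25 and 1, and 8 and 10 with LPS at 20, 44 and 68 h, and 3135 and 42, 132 and 0, and 206 and 4 with anti-IgM. With LPS at 68 h 2 of 10 splits reached the real count. There, and in the OP9 responses, replicate 3 is divergent in both groups, and of the 4 splits that part every pair of replicate numbers the real one gave the highest count (other 0 with LPS, 638 and 1875 in the OP9 responses to LPS and anti-IgM). The responses to LPS gave 4862 and 2520 on OP9 and 1230 and 2 on DL1, and those to anti-IgM 3811 and 4426 on OP9, where 3 of 10 reached the real count, and 1468 and 2 on DL1. Between 20 and 68 h they were 1995 and 297 (LPS) and 1463 and 4712 (anti-IgM, 3 of 10 as large) on OP9, 2945 and 0 and 363 and 1 on DL1, and 443 and 1 for Blimp1+ cells. Of 100 drawn, only the real split reached the mean DL1 effect (2174, highest other 459) and the stimulus difference (1684 and 1390). That split also parts divergent from other libraries at 20 h, so the stroma is not shown as source. Chance is not excluded for the ligand's effect on the response to LPS (5 reached 2574, highest other 4711) or anti-IgM (6, 2497 and 3498). Nor is it for the change over time with LPS (4, 381 and 2630, a share near 0.05) or anti-IgM (40, 1 and 3308). No splits parting replicate numbers were counted for these. Splits that call several times the real count, as in both changes over time and in anti-IgM on OP9 over time, point to a structure of the samples.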

How the results depend on the processing

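Fits without the 10 divergent libraries, with the divergence score as a term, or restricted to 44 and 68 h were chosen after seeing the data. Over the settings fixed beforehand other than left-out libraries, 132 of 201 counts stayed within 1.5 times the main count, and 22 of 22 did so with the replicate block. Of 222 counts with 1 library left out, 147 did. Of 9219 values of named genes over all alternatives 8228 kept direction and call, 956 lost the call, 28 gained it and 7 turned. Of 660 list tests 294 were called, and 135 with an estimated correlation. TPM as deposited called 276 (24 with an estimated correlation) and the score as a term 283. Every same-number correlation of replicates passed 0.1 in 3 of 16 comparisons, those with replicate 3 divergent in both groups. Taking out the score left 0, but the score was built from those groups, so pairing is not excluded. The replicate block gave 8, 4999 and 3928 there, for the DL1 effect with LPS at 68 h and the OP9 responses to LPS and anti-IgM, and 20 of 45 libraries were closest to one of their own number. Depth of 3.07 M to 29.1 M estimated reads limits what can be seen of genes near 1 TPM. Unless stated, the cause of a change was not tested. Counts below are of called genes, "time" means 68 h against 20 h, and "DL1 by" means the difference of a response between stromas.

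Without the 10 divergent libraries, leaving fewer samples, the DL1 effect had 6581 calls unstimulated, 109 with LPS at 44 h, 23 at 68 h, and 911 and 855 with anti-IgM at 44 and 68 h. The response to anti-IgM on OP9 had 6174, those on DL1 2668 (LPS) and 4291 (anti-IgM), DL1 by LPS 4249, DL1 by anti-IgM 5746, time on OP9 with LPS 3433 and time on DL1 with anti-IgM 1704. With no 20 h pair left on one stroma, DL1 effects at 20 h could not be fitted. Over stimulated pairs at 44 and 68 h the mean DL1 effect had 800 calls and the stimulus difference 571, and Dtx1 (-0.09) and Cdkn1a (0.27) turned in the mean. For 68 h against 44 h the change of the DL1 effect had 8 (LPS) and 6 (anti-IgM) calls and time on OP9 with anti-IgM 21. Turned were Cth (-0.37) and Trib3 (-1.75) in the change with LPS, Bub1b (-0.39) and Ccna2 (-0.35) in time on OP9 with anti-IgM, and Yrdc (0.16) in time on DL1 with anti-IgM.

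With the divergence score as a term, DL1 effects had 2502, 58 and 29 calls with LPS at 20, 44 and 68 h, and 315, 437 and 472 with anti-IgM. The responses on DL1 had 2050 (LPS) and 2734 (anti-IgM), DL1 by anti-IgM 3788, the stimulus difference 182, the change over time of the DL1 effect 1822 (LPS) and 5 (anti-IgM), and time had 3206 on OP9 with LPS, 5092 on DL1 with LPS and 1054 on DL1 with anti-IgM.

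Only the groups compared keeps each log2 difference but takes its error from them, so counts fell or rose. The DL1 effect had 1146 calls unstimulated, 201, 122 and 0 with LPS at 20, 44 and 68 h, and 835, 2542 and 0 with anti-IgM. The 0 counts are by limma, where the full model had 497 (LPS) and 2809 (anti-IgM) at an unadjusted p under 0.05. Responses had 1592 (LPS) and 308 (anti-IgM) on OP9 and 295 and 3821 on DL1, DL1 by LPS 881, DL1 by anti-IgM 507, and the change over time 14 and 0. Time had 2 (LPS) and 0 (anti-IgM) on OP9, 1770 and 1783 on DL1, and Blimp1+ cells 187. Here 152 values of named genes lost the call, 7 gained it and 303 kept their status. Those in the text that lost it stand beside their results.

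TPM as deposited gave DL1 effects of 16 and 5 (LPS at 44 and 68 h), 26 and 365 (anti-IgM) and 1449 (mean), changes over time of 179 and 0, and time counts of 1327 (OP9, LPS), 706 (OP9, anti-IgM) and 102 (DL1, anti-IgM). Removing antibody genes gave 15 and 4, 25 and 368, 1376, 153 and 0, and 1318, 660 and 97 in this order, and 161 for Blimp1+ cells. Its all-gene medians mostly followed TPM as deposited, so scaling changed too. The authors' log2 table gave 6 and 1, 8 and 338, and 1222 for the DL1 effects. It gave 2519 for anti-IgM on OP9, 645 for LPS on DL1, 915 for DL1 by LPS, 698 for DL1 by anti-IgM, 208 and 0 for the change over time, 711 and 69 for time with anti-IgM on OP9 and DL1, and 251 for Blimp1+ cells. Each 0 is the change over time with anti-IgM, by limma (1381 genes at an unadjusted p under 0.05 in the main scaling). Quantile normalization gave 13 for LPS at 68 h and 173 for the change over time with LPS.

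A pseudocount of 0.1 gave 12 and 5 for LPS at 44 and 68 h, 1514 for DL1 by anti-IgM, 3 for the change over time with anti-IgM and 263 for Blimp1+ cells. No filter gave 22 for LPS at 68 h, 700 for the stimulus difference, and 235 (LPS) and 2 (anti-IgM) for the change over time. A filter at 5 TPM, which tests fewer genes, gave 1714 for DL1 by LPS. Against DL1 cells with LPS at 44 h, Blimp1+ cells had 1919.

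With 1 library left out, counts ranged from 638 to 1847, 14 to 17 and 5 to 9 for the DL1 effect with LPS at 20, 44 and 68 h, and from 946 to 4149, 26 to 46 and 29 to 446 with anti-IgM. They ranged from 715 to 1050 and 891 to 1195 for the responses to LPS and anti-IgM on DL1, 1498 to 4137 for DL1 by anti-IgM, and 690 to 2844 for the stimulus difference. For the change over time they were 136 to 804 (LPS) and 0 to 56 (anti-IgM), for time with anti-IgM 469 to 3723 on OP9 and 128 to 224 on DL1, and for Blimp1+ cells 257 to 446.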

Other observations

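These observations use lists fixed beforehand, and only tests without divergent libraries were chosen after seeing results. In each 68 h response the class switching and germinal centre list was called upward. With LPS 8 of 18 rose and 3 fell on OP9, and 9 and 3 adjusted over the list alone (median 1, adjusted p = 0.00013, and 0.0017 with an estimated correlation). On DL1 6 rose and 1 fell with LPS, and 8 and 1 adjusted over the list alone (median 0.53, adjusted p = 2.3e-05, and 0.00045 with an estimated correlation). With anti-IgM 10 rose and 2 fell on OP9, and 11 and 4 adjusted over the list alone (median 1.23, adjusted p = 0.0014, and 0.0097 with an estimated correlation), and on DL1 6 rose and 1 fell, the same numbers adjusted over the list alone (median 0.71, adjusted p = 3e-04, and 0.0021 with an estimated correlation). Without divergent libraries the OP9 medians (0.98 with LPS, 1.26 with anti-IgM) were not called with an estimated correlation, while those on DL1 (0.69 and 0.71) were. The stroma list fell in 25 of 26 genes in both OP9 comparisons.

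Cell cycle inhibitors had opposite calls at 44 h, where no library is divergent. On DL1 with LPS they were called upward, with 0 of 17 called by limma (366 genes had an unadjusted p under 0.05) and 1 adjusted over the list alone (median 0.4, adjusted p = 0.0057, and 0.049 with an estimated correlation). With anti-IgM at 44 h the median was -1.03. The DL1 effect with LPS minus that with anti-IgM had a median of 1.07, with 6 of 17 higher and 1 lower, and 10 and 1 adjusted over the list alone (adjusted p = 0.0028, but adjusted p = 0.084 with an estimated correlation), and 0.71 over 44 and 68 h without divergent libraries. In the mean DL1 effect 4 of 17 fell, and 9 adjusted over the list alone (median -0.59, adjusted p = 0.00053, and 0.017 with an estimated correlation). Over the stimulated 44 and 68 h pairs without divergent libraries the list median was -0.23, not called with an estimated correlation, and Cdkn1a had 0.27. Between 20 and 68 h with LPS on DL1 5 of 17 rose, and 8 adjusted over the list alone (median 1.31, adjusted p = 4e-04, and 0.029 with an estimated correlation), where all 3 libraries at 20 h are divergent, and the median was 0.85 from 44 to 68 h without divergent libraries.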
